A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

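The series followed Ty1, a copia-type retrotransposon of budding yeast, in the haploid laboratory strain BY4741 (Saccharomyces cerevisiae, MATa, with deletions at HIS3, LEU2, URA3 and MET15). It comprised 23 samples. Of these, 21 were MNase-seq samples in 8 groups, a nucleosome mapping assay in which micrococcal nuclease trims the DNA between nucleosomes, and they were not analysed here. The other 2 samples were Ty1 insertion-profiling libraries, 1 from cells held for 24 h in 2% galactose and 1 from cells held for 24 h in 2% dextrose, both carrying the plasmid pJEF2365. Per the labels' protocols, cells were precultured in medium with 2% raffinose and 0.1% dextrose, moved to the test sugar, and then grown for 24 h in dextrose without selection. They were next grown in dextrose with 1 mg/mL 5-FOA, a compound that kills cells with a working URA3 gene, for 24 h and again for 24 h. The samples' treatment field names complete medium for the induction while the growth protocol names medium without uracil, and which of these was used is not settled here.

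Per the labels' protocols, genomic DNA was cut with MseI, an adaptor was ligated, the product was cut with BglII, and fragments were amplified by PCR between a site named SSB and the adaptor, then selected by size between 200 and 1000 bp. Per the submitters' processing notes, the tools were Trimmomatic 0.39, BWA 0.7.19, SAMtools 1.22, bedtools 2.31.1 and Picard 3.4.0, with the R64 (sacCer3) build. Their settings are not given in the sources used here. Each deposited file lists aligned reads as genomic intervals with a start, an end, a strand and a mapping quality score, and the authors applied no normalization to these positions. The score deposited with each interval ranged from 30 to 60 in both files, so no interval lay under 30. The names the authors gave the files state that duplicate reads were removed, and a position therefore counts about once whatever the number of cells that carried the insertion. Read names in both files carried 1 and the same instrument run and lane.

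An insertion site was defined as a distinct combination of chromosome, strand and 5′ end of the interval, on the 16 nuclear chromosomes. Gene positions came from a RefSeq gene table of the same R64 build, which held 275 nuclear tRNA genes and 6002 nuclear protein-coding genes, and the strand was read from the systematic gene name. Coordinates are given 1-based. A site was counted at a tRNA gene when it lay within 1 kb upstream of the gene's 5′ end, and a site in the windows of neighbouring tRNA genes counted for each gene in per-gene counts and once in shares. The profile of distances used 10 bp bins. Its dominant spacing was the highest autocorrelation peak between lags of 40 and 250 bp after smoothing over 10 bp and removal of the local mean.

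With 1 library per medium there was no replicate spread, so no test between media was made and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals, counts carry exact Poisson 95% intervals, and the difference between shares carries a Newcombe 95% interval. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A count of 0 was read as a limit of 3 counts, or 0.00197% of the galactose sites and 0.0268% of the dextrose sites. Each library was also set beside 1000 random placements of the same number of sites. Placement matched to the distance from the next MseI site was planned, but no genome sequence was used here, and placement was uniform over 12069662 nuclear positions. Differences in how well positions can be recovered or mapped are therefore not taken into account. A planned summary by tRNA amino acid was not run, because the gene table used here gives no amino acid and 47 of the 275 genes have a symbol other than the systematic name.

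The gene lists were fixed before the data were examined: 13 galactose genes, 10 histone genes, 132 ribosomal protein genes, 22 genes of glycolysis and fermentation, 18 hexose transporter and sensor genes, 59 genes of essential complexes, 15 heat shock genes, 12 genes transcribed by RNA polymerase III other than tRNA genes, and the 4 deleted marker genes. All members were found in the gene table. The named genes followed a rule also fixed then: the 10 tRNA genes with the most galactose sites, the 5 with the most dextrose sites, those with 0 galactose sites, the 5 protein-coding genes with the most galactose sites in the gene body and the 5 with the most in the 500 bp upstream among genes with no tRNA gene within 2 kb, the 5 positions with the most reads in each library, and the members of the RNA polymerase III, galactose and marker lists. The alternatives set beforehand covered the minimum number of reads per site, the merging of close sites, the end of the interval used, the window, reads in place of sites and the removal of single regions. The restriction to intervals of 96 bases, or of at most 49 or 96 bases, and the restriction of gene lists to sites beyond 2 kb of any tRNA gene, the comparison of lists with 10000 random lists of protein-coding genes the thinning of the galactose upstream sites, the random placements matched on upstream sites and the 96-base difference without shared sites were chosen after seeing the data. The rule that weighs growth medium as an explanation of the dextrose share was changed after its values were known. The 96-base difference alone excluded it at first, a condition without shared sites was then tried for it and for restriction-site starts and dropped because removing shared sites sets the sign, and the rule used here excludes it only where same-position sharing does not exceed opposite-orientation sharing, which left it open.

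Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. In 150000 simulated sites, the size of the galactose library, a tRNA-upstream share of 41.3% was recovered as 41.3% and a spacing of 180 bp as 180 bp. In 11000 simulated sites, the size of the dextrose library, the same share was recovered as 42.3% and the spacing as 180 bp. The simulated spacing was far more regular than the real one, with autocorrelations of 0.804 and 0.795 against 0.308 in galactose and 0.159 in dextrose. Its recovery therefore does not test spacing that weak. Of 100 simulated libraries of each size, the 95% interval held the true share in 94 and 95. A planted sharing of 50% between libraries was recovered as 57.1%, as 14.1% of independent simulated sites coincided.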

Results

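Ty1 insertion sites were profiled in 2 libraries from BY4741 cells carrying the plasmid pJEF2365, 1 grown for 24 h in galactose, the sugar that the series title names as the inducer of Ty1 expression, and 1 grown for 24 h in dextrose. The galactose library held 170698 aligned intervals and the dextrose library 11577. These gave 152129 distinct nuclear sites (95% interval 151365 to 152895) in galactose and 11208 (95% interval 11001.5 to 11417.5) in dextrose, a 13.6-fold difference. A site was covered by a mean of 1.12 intervals in galactose and 1.03 in dextrose, so almost every site rested on a single interval. The intervals differed 14.7-fold, and the number of reads sequenced per library was not used here. The difference in sites therefore does not by itself measure how the medium changed the number of insertions. As each medium had 1 library, differences between the libraries have no replicate check, and the intervals given cover counting error only.

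The first comparison asked where Ty1 inserted relative to tRNA genes, which are transcribed by RNA polymerase III and are the known main targets of Ty1. In both libraries sites were concentrated upstream of tRNA genes. In galactose 58765 of the 152129 sites, 38.6% (95% interval 38.4 to 38.9), lay within 1 kb upstream of a nuclear tRNA gene, against a mean of 2.23% in random placements, a 17.3-fold excess. In dextrose 2367 of 11208 sites, 21.1% (95% interval 20.4 to 21.9), lay there, a 9.47-fold excess over random placement. The 1 kb downstream of tRNA genes held 9.60% of the galactose sites and 4.26% of the dextrose sites, against 2.21% and 2.22% at random. No random placement reached either upstream share, the highest being 2.34% and 2.64%. Duplicate reads had been removed by the authors, and no site carried more than 1 interval of 96 bases, so a threshold on reads selects intervals of intermediate length. Among positions with at least 2 reads the share was 3.91% (95% interval 3.57 to 4.27) in galactose and 2.84% (95% interval 1.31 to 5.32) in dextrose, the latter including the random level, and among the 447 galactose positions with at least 5 reads it was 1.12% (95% interval 0.364 to 2.59).

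Over all intervals the galactose share exceeded the dextrose share by 17.5 percentage points (95% interval 16.7 to 18.3). The direction depended on the length of the aligned interval. Among full-length intervals of 96 bases, the share was 48.9% (95% interval 48.6 to 49.3) in galactose and 54.9% (95% interval 53.1 to 56.7) in dextrose, a difference of -5.97 percentage points (95% interval -7.81 to -4.12). Among intervals of 50 to 95 bases it was 23.7% in galactose and 8.03% in dextrose. These intermediate intervals made up 48.9% of the galactose intervals and 71.0% of the dextrose intervals, and full-length intervals made up 43.5% and 25.0%. Among intervals of at most 49 bases the share was 53.7% in galactose and 34.3% (95% interval 29.9 to 39.0) in dextrose. The split by length was chosen after seeing the data. A position counts once however often it was hit, and galactose had 36323 upstream sites of 96 bases against 1588 in dextrose. Often-hit positions next to tRNA genes can thus be undercounted more in galactose. Whether this accounts for the reversed direction was not tested.

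**Figure D1:**
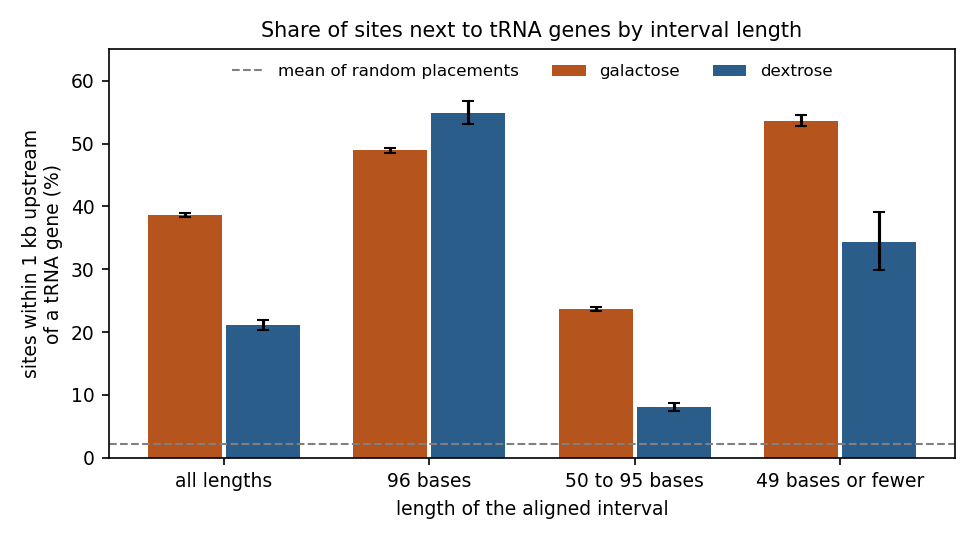
Percentage of distinct sites within 1 kb upstream of a nuclear tRNA gene (vertical axis) for all intervals and for 3 classes of interval length (horizontal axis) in the galactose and dextrose libraries, with exact 95% binomial intervals as error bars and the mean of random placements as a dashed line. Galactose is higher over all lengths (38.6% against 21.1%), and dextrose is higher among intervals of 96 bases (54.9% against 48.9%).

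Nearly all tRNA genes had sites. In galactose 273 of the 275 nuclear tRNA genes had at least 1 site in the upstream 1 kb, with a median of 213 sites per gene (quartiles 132 and 310). In dextrose 260 genes had a site, with a median of 7 (quartiles 3 and 12). When the galactose sites were subsampled to 11208, a mean of 268.7 genes (range 263 to 272 over 1000 draws) had a site, but that set keeps the higher galactose share upstream. With the galactose upstream sites subsampled to the 2367 of dextrose, a setting added after seeing the data, the mean was 263.9 genes (range 258 to 270 over 100 draws), and the 260 of dextrose lay within that range. Of the genes, 13 had sites in galactose only, none in dextrose only, and 2 in neither, namely YNCC0008W (chromosome III, 149920 to 149991) and YNCN0008C (chromosome XIV, 519099 to 519169). As far as counting goes, a 0 allows up to 3 sites at each of them. All intervals had a mapping score of at least 30, and whether reads can be placed in these windows was not examined. The 0 counts may therefore not show an absence of insertions.

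The 2 tRNA genes with the most galactose sites were neighbours on chromosome IX that point away from each other. YNCI0008C (324303 to 324374) had 670 sites (95% interval 620 to 723) and YNCI0009W (325748 to 325820) had 623. A similar divergent pair on chromosome VIII, YNCH0004C (133026 to 133107) and YNCH0005W (134321 to 134392), had 520 and 488 sites. The windows of each pair overlap, and a site in the overlap counts for both genes. The other genes among the 10 highest were YNCG0029C (513 sites) and YNCG0009C (488) on chromosome VII, YNCB0004W (511) on chromosome II, YNCJ0011W (502) on chromosome X, YNCL0040W (501) on chromosome XII and YNCF0008C (477) on chromosome VI. In dextrose the 5 highest were YNCJ0011W and its neighbour YNCJ0012W (355456 to 355527) with 39 sites each, YNCG0042C (chromosome VII, 878710 to 878815) with 37, YNCB0004W with 33 and YNCF0008C with 31. The windows of YNCJ0011W and YNCJ0012W overlap over most of their length, and a site in the overlap counts for both. Of the 10 highest genes in galactose, 4 were also among the 10 highest in dextrose.

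Across the 275 tRNA genes, the numbers of sites in the libraries were correlated (Pearson r = 0.762, Spearman rho = 0.790). Genes are not independent replicates, so these values only describe the libraries. Without the dextrose sites that were also present in galactose, r was 0.254 and rho 0.313. That removal took 2145 of the 2367 dextrose upstream sites and left 222 over the 275 genes. Counts that low, and a removal more likely where galactose sites are dense, lower both values by construction. The fall therefore does not show what the agreement rests on.

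**Figure D2:**
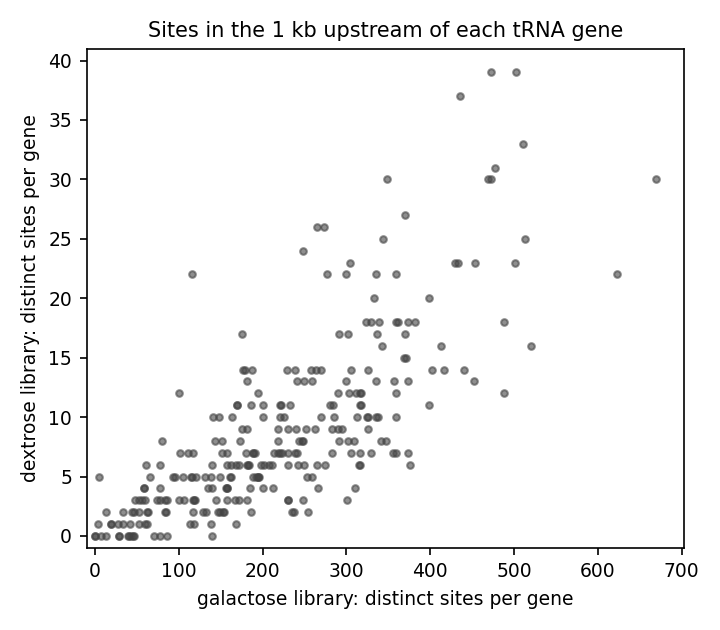
Distinct sites in the 1 kb upstream of each of the 275 nuclear tRNA genes (1 point per gene) in the galactose library (horizontal axis) and the dextrose library (vertical axis), without error bars. Genes with more galactose sites tended to have more dextrose sites (Pearson r = 0.762), with maxima of 670 and 39 sites.

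The distance profile asked how sites were placed relative to the start of the tRNA gene, a question tied to nucleosomes because the series maps them in the same strain. Sites were sparse next to the gene, with 202 of the 58765 upstream sites in galactose and 14 of the 2367 in dextrose within 60 bp. The galactose profile then peaked at 91 to 100 bp (1628 sites per 10 bp), 171 to 180 bp (1433), 271 to 280 bp (1060), 351 to 360 bp (959), 511 to 520 bp (731) and 631 to 640 bp (513). In dextrose the peaks were at 101 to 110 bp (134 sites), 171 to 180 bp (109), 261 to 270 bp (43), 351 to 360 bp (49), 451 to 460 bp (34), 511 to 520 bp (27) and 651 to 660 bp (18). The dominant spacing in galactose was 184 bp (bootstrap 95% interval 182 to 185) with an autocorrelation of 0.308. In dextrose the estimate was 183 bp, with a bootstrap interval from 82 to 249 bp and an autocorrelation of 0.159. Random placements over the genome reached these autocorrelations in 1 of 1000 cases for galactose and 511 for dextrose, but they put only 2.23% of their sites upstream and so are noisier than the real profiles. Placements with the number of upstream sites matched, added after seeing the data, reached the galactose value in 2 of 1000 cases when even within the windows and in 53 when they followed the profile smoothed over 301 bp, and the dextrose value in 390 and 617. A mean over 301 bp does not fully remove a repeat of 184 bp. How far the galactose spacing stands out thus depended on the placement, and no spacing stood out in dextrose. Galactose upstream sites thinned to the 2367 of dextrose, a setting added after seeing the data, gave 184 bp (95% of 1000 draws between 174 and 195) with a median autocorrelation of 0.245, and 48 draws had an autocorrelation at or below that of dextrose.

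Dextrose sites lay closer to the tRNA gene. The median distance within the upstream 1 kb was 345 bp (95% interval 343 to 348) in galactose and 245 bp (95% interval 230 to 261) in dextrose. The first 200 bp held 29.2% (95% interval 28.8 to 29.5) of the upstream sites in galactose and 44.1% (95% interval 42.1 to 46.2) in dextrose. Among intervals of 96 bases the medians were 350 and 254.5 bp. A position counts once however often it was hit, and galactose had 58765 upstream sites against 2367 in dextrose. Often-hit positions near the gene can thus be undercounted more in galactose. Whether this accounts for the difference in distance was not tested. Sites lay slightly more often on the strand of the tRNA gene than on the opposite strand, 52.0% (95% interval 51.6 to 52.4) in galactose and 55.0% (95% interval 53.0 to 57.0) in dextrose.

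**Figure D3:**
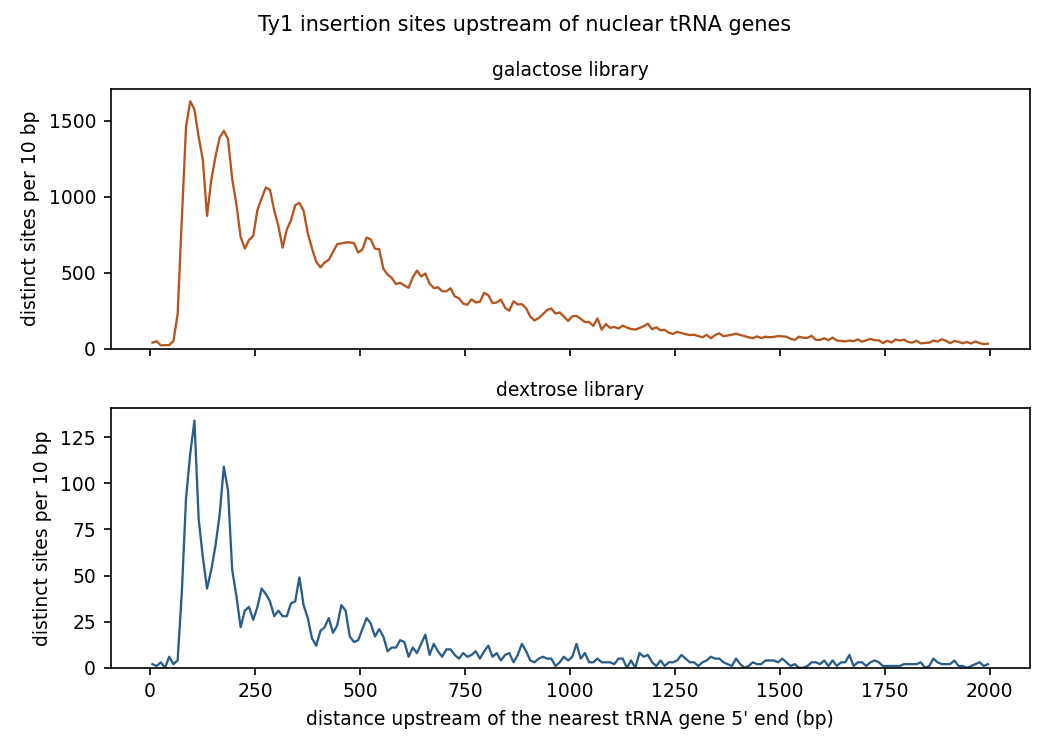
Number of distinct sites per 10 bp (vertical axis, a separate scale for each library) by distance upstream of the 5′ end of the nearest nuclear tRNA gene in bp (horizontal axis), in the galactose library (top) and the dextrose library (bottom). The highest bins are 91 to 100 bp (1628 sites) in galactose and 101 to 110 bp (134 sites) in dextrose, and smaller peaks follow farther upstream in both.

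Other genes transcribed by RNA polymerase III also had sites upstream. The 12 listed genes together had 1052 sites in their upstream 1 kb in galactose (95% interval 989 to 1118) against a mean of 151 at random, and 53 in dextrose (95% interval 39.7 to 69.3) against 10.8. SCR1 (chromosome V, 441987 to 442508), the RNA of the signal recognition particle, had 377 sites in galactose and 17 in dextrose. The tRNA gene YNCE0025C (443202 to 443275) lies 694 bp from its 3′ end, and the upstream window of that tRNA gene does not overlap the window counted for SCR1. SNR6 (chromosome XII, 366235 to 366346), the U6 spliceosomal RNA, had 280 and 14, SNR52 (chromosome V, 431129 to 431220), a small nucleolar RNA, had 191 and 14, and RPR1 (chromosome V, 117667 to 118035), the RNA of RNase P, had 164 and 5. At each of these 3 genes a uniform placement gives 12.6 and 0.929 sites. RNA170 (chromosome XIII, 667288 to 667456) had 20 galactose sites (95% interval 12.2 to 30.9) and ZOD1 (chromosome XIII, 91970 to 92027) had 18 (95% interval 10.7 to 28.4), with 2 and 1 in dextrose. Both galactose intervals include the 12.6 sites of uniform placement. The upstream windows of the 5S rRNA genes RDN5-1, RDN5-2, RDN5-3, RDN5-5 and RDN5-6 had 0 sites in both libraries and RDN5-4 had 2 in galactose and 0 in dextrose, where a read from the repeated rDNA cannot be placed on 1 copy. The rDNA spacer downstream of RDN5-1 (chromosome XII, 459797 to 460711) held 538 galactose sites and 108 dextrose sites. Reads from other copies of the repeated rDNA may be placed there, so these counts cannot be compared with those of single genes.

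Protein-coding sequence held fewer sites than its share of the genome. In galactose 39.0% of sites (95% interval 38.7 to 39.2) and in dextrose 58.5% (95% interval 57.6 to 59.5) lay inside a protein-coding gene, against 72.8% in random placements. Beyond 2 kb of any tRNA gene the shares were 63.6% (95% interval 63.23 to 63.95) in galactose and 74.2% (95% interval 73.2 to 75.2) in dextrose, against 74.6% at random. The dextrose share there was within the range of random placements (72.8% to 76.1%). Among full-length intervals in the same regions it was 54.8% in galactose and 61.7% (95% interval 58.5 to 64.8) in dextrose.

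Gene lists were compared beyond 2 kb of any tRNA gene, a restriction chosen after seeing the data because sites at tRNA genes lower the density elsewhere. In galactose the upstream 1 kb of the 13 galactose genes held 280 sites against a mean of 69.5 at random. The counts that follow sum the windows of single genes, so a site in the windows of several genes counts for each, and are set against uniform placement counted in the same way. Upstream regions in general held more sites than uniform placement gives, with a ratio of 1.23 over all protein-coding genes. Against that level the 22 genes of glycolysis and fermentation (211 sites against 137, a ratio of 1.54), the 132 ribosomal protein genes (1006 against 807, a ratio of 1.25) and the histone genes (83 against 62.9, a ratio of 1.32) lay within the central 95% of 10000 random gene lists of their size, at percentiles 93.2, 63.7 and 68.5. The same held for the essential complexes (the chaperonin TRiC, the proteasome and the nuclear RNA polymerases; 366 against 331), the heat shock genes (103 against 94.4) and the hexose transporters and sensors (108 against 113), at percentiles 16.6, 31.6 and 9.57. The galactose genes were above the central 95% (0.782 to 1.83) with 402 sites against 73.7, a ratio of 5.46, in which a site between GAL1 and GAL10 counts for each gene. Over all sites, those at tRNA genes included, the upstream ratios of the histone, ribosomal protein and glycolysis lists to uniform placement were below 1 (0.710, 0.776 and 0.770).

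Gene bodies in general held fewer sites than uniform placement gives, with a ratio of 0.850 over all protein-coding genes, or 0.733 among intervals of 96 bases. The essential complexes had 394 galactose sites against 473 under uniform placement, which is 0.981 of the level of all genes. Among intervals of 96 bases they had 89 sites against 164, a ratio of 0.544, or 0.743 of the level of all genes, at percentile 3.06 of random gene lists and within their central 95% (0.538 to 1.04). Ribosomal protein gene bodies had 605 sites, 1.17 times the level of all genes and above the central 95% of random lists. Of these sites, 58 lay in the single gene RPL15A, where uniform placement gives 7.75. The list without RPL15A was not compared with random lists, so the excess may rest on that gene. Bodies of the galactose genes had 222 sites, 2.07 times the level of all genes and also above the central 95% of random lists. The hexose transporters and sensors (163), heat shock (119), glycolysis (173) and histone (26) gene bodies lay within the central 95% of random lists. Among intervals of 96 bases the glycolysis gene bodies were above it as well, with 81 sites, a ratio of 1.21 against a range of 0.438 to 1.18, at percentile 97.78. In dextrose, over all intervals, each of the 7 lists lay within the central 95% of random placements, upstream and in gene bodies, at counts between 1 and 99 sites, with the 14 sites upstream of galactose genes on the upper limit of 14. Among 96-base dextrose intervals 2 counts were above the limits of uniform random placements, 4 sites upstream of galactose genes (limit 3.025) and 7 in hexose transporter and sensor bodies (limit 6). These limits do not allow for the general excess that upstream regions had in galactose. No correction was made for the number of lists, gene parts and interval classes compared, so some values outside a central 95% can arise by chance.

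The galactose genes encode the enzymes, transporter and regulators of galactose use and related targets. Of their 280 upstream sites, 188 lay in the 1 kb upstream of GAL1, which takes in the start of GAL10, and of their 222 gene body sites 107 lay in GAL10. The intergenic region shared by GAL1 and GAL10 (chromosome II, 278353 to 279020), which drives galactokinase in one direction and the epimerase in the other, held 122 galactose sites (95% interval 101 to 146) where uniform placement gives 8.42, and 5 dextrose sites (95% interval 1.62 to 11.7) where it gives 0.620. The first 200 bp of GAL10 held 65 galactose sites, or 325 per kb, while the rest of GAL10 held 22.1 per kb. The first 1 kb of GAL1 held 5 sites. In the 500 bp upstream of GAL7 there were 8 galactose sites, upstream of GAL2 5, GAL3 4, GCY1 3, PGM2 3 and GAL80 1, against a median of 3 and an upper limit of 13 for the central 95% of genes beyond 2 kb of a tRNA gene. Over the upstream 1 kb, MTH1 had 23 sites, LAP3 13, FUR4 12, GAL4 9 and PCL10 4. Gene bodies on the list other than GAL10 held from 1 site in LAP3 to 24 in GAL4.

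The labels give the strain as deleted at URA3, LEU2 and MET15, so sites in these genes report on DNA other than its own chromosome or on misplaced reads. Its his3 deletion is known to be partial, so sites in HIS3 can lie on the chromosome. URA3 (chromosome V, 116167 to 116970) held 126 galactose sites (95% interval 105 to 150) where uniform placement gives 10.1, and 11 dextrose sites (95% interval 5.49 to 19.7) where it gives 0.747. LEU2 (chromosome III, 91324 to 92418) held 5 and 1, HIS3 (chromosome XV, 721946 to 722608) held 3 and 0, and MET15, listed as MET17 (chromosome XII, 732542 to 733876), held 0 in both.

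**Figure D4:**
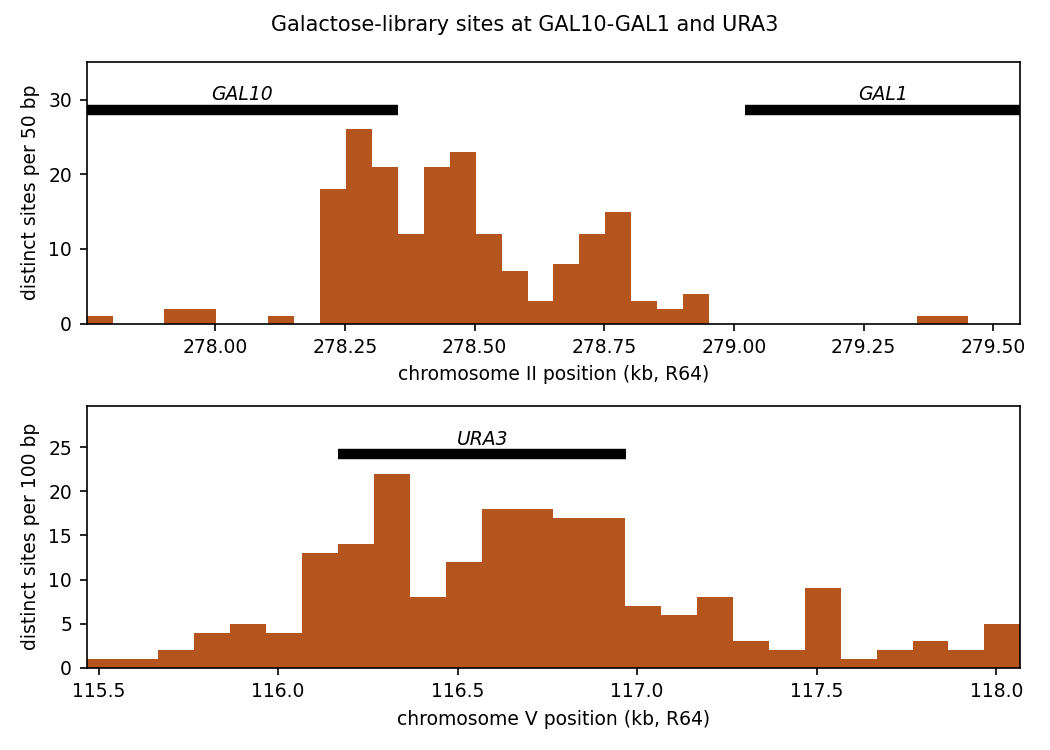
Distinct galactose-library sites (vertical axis) per 50 bp across GAL10 and GAL1 on chromosome II (top) and per 100 bp across URA3 on chromosome V (bottom), by R64 position in kb (horizontal axis), with genes as black bars cut at the edge of the region. Sites fill the GAL10 to GAL1 intergenic region (122 sites) and the first 200 bp of GAL10 (65 sites), and URA3 holds 126 sites.

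Among the 5337 protein-coding genes with no tRNA gene within 2 kb, the most galactose sites in the gene body were in URA3 (126), GAL10 (107), REA1 (77), DYN1 (59) and RPL15A (58). REA1 (chromosome XII, 349006 to 363738) and DYN1 (chromosome XI, 535647 to 547925) are long genes whose counts were below the 186 and 155 of uniform placement. RPL15A (chromosome XII, 201976 to 202590), a ribosomal protein gene, exceeded its 7.75. In the 500 bp upstream, the highest were GAL10 (116), PMD1 (73), TIM9 (63), GAL1 (59) and RTT101 (40), against 6.30 under uniform placement. The PMD1 window lies 180 bp from SNR52. The TIM9 window overlaps URA3, with 46 of its 63 sites inside that gene, and lies 457 bp from RPR1, and the RTT101 window lies 1636 bp from a tRNA gene. The positions with the most reads in galactose were in the rDNA spacer at 460253 (33 reads), 460065 (22) and 460250 (15) on chromosome XII, and in the GAL1 to GAL10 region at 278525 (17) and 278452 (15) on chromosome II. In dextrose no position had more than 3 reads, and the 5 listed lay in ALK2, OAC1, TEX1, PEX11 and IRA2. Duplicate reads had been removed, so these read counts do not measure how abundant a position was.

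The last comparison asked how many dextrose sites coincided with galactose sites. Of the 11208 dextrose sites, 6400 (57.1%, 95% interval 56.2 to 58.0) were at the same position and strand as a galactose site, against a mean of 3.47% when sites were redrawn at random within tRNA windows and elsewhere. Within the tRNA windows 90.6% (95% interval 89.4 to 91.8) coincided, against 14.9% at random, and elsewhere 48.1% (95% interval 47.1 to 49.2), against 0.399%. The random level spreads sites evenly within each class and ignores the peaks in the profile. Among 96-base dextrose sites, 92.8% coincided in tRNA windows and 30.7% (95% interval 28.2 to 33.2) elsewhere, with 20.7% beyond 2 kb of a tRNA gene, while positions shifted by 1 base coincided at 47.2%, 12.7% and 10.8%. Among intervals of 50 to 95 bases, 51.9% (95% interval 50.7 to 53.1) coincided outside tRNA windows, and among those of 78 bases 85.9% of all sites did with a galactose interval of the same length. Of the dextrose sites absent from galactose, 4.62% (95% interval 4.04 to 5.25) lay in the 1 kb upstream of a tRNA gene. The removal of coinciding sites itself lowers that share, as it took 90.6% of the sites in tRNA windows but 48.1% elsewhere.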

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

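The counts in the deleted genes and in mitochondrial DNA were planned before the data were examined, while the tests of the 3 patterns weighed in this part were chosen after their results had been seen. Signal was present in sequence outside the nuclear insertion measurement. Of URA3, which the strain lacks, 126 galactose sites and 11 dextrose sites were above the 3 that a count of 0 allows. LEU2, also deleted, held 5 galactose sites (95% interval 1.62 to 11.7), where uniform placement gives 13.8. The mitochondrial chromosome held 300 galactose intervals (0.176% of all) and 46 dextrose intervals (0.397%).

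The dextrose library had a lower share of sites next to tRNA genes. Among intervals of 96 bases the difference was -5.97 percentage points (95% interval -7.81 to -4.12). A difference at or below 0 would be seen if that library held a larger load of intermediate intervals that begin at restriction sites instead of a Ty1 end. Undercounting of often-hit positions next to tRNA genes in galactose, with 36323 such upstream sites against 1588, could also lower the difference. How much it does was not tested. The 78-base dextrose intervals began in 188 opposite-strand pairs overlapping by 6 bases, the length of the BglII site, and in 0 pairs at other overlaps. In galactose 486 pairs of 78-base starts overlapped by 6 bases. Of the 54-base dextrose intervals, 3.01% (95% interval 2.34 to 3.82) began exactly where a short galactose interval ended, as an MseI cut would give. This compares with 0.207% (95% interval 0.0761 to 0.451) of the 96-base dextrose intervals and 2.29% (95% interval 1.80 to 2.87) of the 54-base galactose intervals. Both traits were thus present in both libraries and do not by themselves show a larger load in dextrose. Intervals of 54 bases made up 19.1% of the dextrose and 1.88% of the galactose intervals, and those of 78 bases 13.2% and 2.41%. Growth medium stays open, as each medium had 1 library and most 96-base dextrose sites in tRNA windows coincided with galactose sites (92.8%, against 64.4% in the opposite orientation), so that the -5.97 may not measure insertion in dextrose. Also open is how many intermediate intervals mark real insertions, since 23.7% of them in galactose lay next to tRNA genes, as does the higher galactose share among intervals of at most 49 bases (53.7% against 34.3%), and the restriction sites themselves were not read because no genome sequence was used here.

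Dextrose sites often coincided exactly with galactose sites. Of the 96-base dextrose sites in tRNA windows, 92.8% (95% interval 91.4 to 94.0) had a galactose site at the same position and strand. In the opposite orientation at the same 5 bp target, 64.4% (95% interval 61.9 to 66.7) had one (47.2% for a position 1 base away). Repeated use of a target regardless of orientation would give equal shares only if both orientations were recovered equally well. Their reads run to MseI sites on different sides of the target, and differences in recovery were not taken into account. The lower opposite share therefore cannot decide whether repeated use of a target is the cause. A preference that differs by orientation was not tested and stays open. Of the 96-base dextrose sites absent from galactose, 11.2% (95% interval 9.32 to 13.3) lay next to tRNA genes, against 2.64% in the highest random placement of all dextrose sites. Removing the coinciding sites itself lowers the 11.2%. Whether the shared sites were insertions present in both cultures from the start or reads crossing between libraries cannot be told apart, because both libraries were on 1 lane, the labels do not say whether the cultures came from a single preculture, and a galactose insertion can be missed by sequencing.

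Galactose sites clustered between GAL10 and GAL1. The density fell 14.7-fold from the first 200 bp of GAL10 to the rest of the gene, which together with the 126 sites in URA3 is consistent with insertions into a second copy of the promoter on a plasmid. The 8 sites upstream of GAL7 and 5 upstream of GAL2, under the upper limit of 13 for the central 95% of genes, argue against a general uptake by galactose-induced promoters. The sequence of pJEF2365 was not used here, and an insertion that disrupts a plasmid URA3 could also let a cell survive 5-FOA, which was not tested. If the plasmid carries an intact URA3, 5-FOA would kill cells that kept it. How insertions into a promoter copy on such a plasmid would then be recovered was not tested.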

How the results depend on the processing

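The settings restricted to certain interval lengths or to sites beyond 2 kb of a tRNA gene, the thinned profile and occupancy, the matched placements for the spacing and the lists relative to all protein-coding genes were chosen after seeing the data, and the others before the data were examined. Of 144 alternatives computed over 33 results, 52 left the value within its interval or within 1.5 times the count, 80 moved it and 12 reversed a direction. The upstream excess at tRNA genes held in direction under each window and under both length restrictions run as alternatives, with shares from 16.9% to 54.9% (dextrose intervals of 50 to 95 bases alone gave 8.03%), and the read thresholds do not test it: after the removal of duplicates no site carried more than 1 interval of 96 bases, so 87.9% of galactose and 94.6% of dextrose positions with at least 2 reads had a longest interval of 50 to 95 bases. The galactose spacing (183 to 185 bp) stayed within its interval, but its autocorrelation was reached by 1 of 1000 genome-wide placements, 2 even placements and 53 placements following the smoothed profile.

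With at least 2 reads per site, which selects that class, the sites numbered 11849 in galactose and 317 in dextrose, the tRNA-upstream share was 3.91% and 2.84% (difference 1.07 percentage points, 95% interval -1.42 to 2.46), the coding share 73.9% and 77.0%, dextrose tRNA genes with a site 11, and dextrose sites shared with galactose 59.3%. With at least 5 reads, 447 galactose sites remained, 1.12% of them upstream of a tRNA gene, and no dextrose site. Merging sites within 5 bp left 84228 in galactose by construction. Reads in place of sites gave a galactose tRNA-upstream share of 34.8%, a difference of 14.2 percentage points and a galactose coding share of 42.8%. The 500 bp window gave 26.4% and 16.9% (difference 9.50) and the 2 kb window 44.2% and 23.7% (difference 20.4), as windows of other sizes must. The 3′ end as position gave 27.9% and 19.6%. Without sites present in both libraries the difference was 34.2 percentage points, or 37.0 with only 96-base intervals, a sign set by the removal itself (92.8% of the 96-base dextrose sites in tRNA windows but 30.7% elsewhere), and the per-gene correlation without shared dextrose sites was 0.254. That correlation rested on the 222 dextrose upstream sites that remained, and the removal itself lowers it. Within 500 bp, 53.2% of galactose sites were on the strand of the tRNA gene. Outside the 2 kb upstream of tRNA genes the coding shares were 59.9% and 73.2%. Within 5 bp, 75.2% of dextrose sites coincided with a galactose site.

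Only intervals of 96 bases left 74253 and 2893 sites, tRNA-upstream shares of 48.9% and 54.9%, a reversed difference of -5.97 percentage points, coding shares of 30.03% and 28.6%, 615 galactose sites upstream of other RNA polymerase III genes, a galactose median distance of 350 bp, 51.4% on the tRNA strand in galactose and 64.8% of dextrose sites shared. Adding intervals of at most 49 bases gave 86789 and 3323 sites, shares of 49.6% and 52.2%, a reversed difference of -2.59 percentage points, coding shares of 28.9% and 29.7%, a median of 349 bp and 63.1% shared. Beyond 2 kb of a tRNA gene, and there with 96-base intervals, the galactose-library ratios to random placement were 1.76 and 2.06 for galactose gene bodies, 4.03 and 4.31 upstream of galactose genes, 0.836 and 0.544 for essential complex bodies, and 1.12 and 1.07 upstream of essential complexes. Upstream ratios that had been below 1 over all sites reversed to 1.42 and 1.67 for histone genes, 1.26 and 1.26 for ribosomal protein genes and 1.53 and 2.29 for glycolysis, and to 1.53 for heat shock genes with 96-base intervals. Relative to all protein-coding genes the ratios were 2.07 for galactose gene bodies, 4.45 upstream of galactose genes and 0.981 for essential complex bodies, with reversals to 0.902 upstream of essential complexes, 1.17 for ribosomal protein gene bodies and 1.25 upstream of glycolysis genes. The value for ribosomal protein gene bodies includes the 58 sites of RPL15A, where uniform placement gives 7.75, and was not computed without that gene. Except where the construction shows it, the cause was not tested.

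No paired analysis was possible because each medium had 1 insertion library and the replicate numbers belong to MNase-seq groups not analysed here; for the same reason leaving out a replicate was not possible. Placement matched to MseI sites was not run, uniform placement being the main setting, and a minimum mapping score of 30 removed no interval. The dextrose spacing had a bootstrap interval of 82 to 249 bp, and draws of the galactose profile thinned to the same 2367 upstream sites ranged from 174 to 195 bp, with 48 of 1000 draws at or below the dextrose autocorrelation, so whether the number of sites accounts for it stays open. Thinned to as many upstream sites, galactose had sites at a mean of 263.9 tRNA genes.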

Other observations

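The tests and windows in this part were chosen after seeing the data. Away from tRNA genes and other RNA polymerase III genes, a few 1 kb windows held many more galactose sites than the mean of 6.13 per kb. After the GAL10 window with 188, they were 2 adjacent windows at the right end region of chromosome III, 299001 to 300000 with 99 sites and 298001 to 299000, at the glycerophosphoinositol transporter gene GIT1, with 95. A window at 291001 to 292000 on the same chromosome held 65. These 3 lie between 2445 and 3484 bp from a tRNA gene. The window at RPL15A (chromosome XII, 202001 to 203000) held 62, that at ATG18 (chromosome VI, 194001 to 195000) held 45, and that at PAU13 (chromosome VIII, 11001 to 12000), 50755 bp from the nearest tRNA gene, held 40.

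The 2 kb at each chromosome end held 0.191% of the galactose sites (95% interval 0.170 to 0.215) and 1.19% of the dextrose sites (95% interval 0.994 to 1.40), against 0.530% under uniform placement. Among dextrose intervals of at most 49 bases it was 8.82% (95% interval 6.31 to 11.9), or 38 of 431 sites. Among those of 96 bases it was 0.518% (95% interval 0.290 to 0.854), or 15 of 2893 sites, at the uniform level. Opposite-strand starts of 96-base galactose intervals overlapped by 5 bases, the length of the target-site duplication of Ty1, in 6718 pairs, against a median of 2754.5 pairs at other overlaps. Positions with at least 2 reads numbered 11849 in galactose, of which 87.9% had a longest interval of 50 to 95 bases and 3.91% lay next to tRNA genes. Positions with 1 read had 39.1% and 41.6%. As duplicates had been removed, the lengths at 11756 of the 11849 positions all differed, so the read count selects the length class.

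Sites in essential genes were examined for a hypothesis that haploid cells with an insertion in an essential gene were lost, and that intervals of 50 to 95 bases mostly do not mark insertions. Beyond 2 kb of a tRNA gene, essential complexes made up 0.914% of coding positions. They held 0.677% (95% interval 0.544 to 0.832) of the coding sites of 96-base galactose intervals and 0.995% (95% interval 0.886 to 1.11) of those of 50-to-95-base intervals, a difference of -0.318 percentage points (95% interval -0.491 to -0.130). The first share is below that of positions by more than counting error, but 3.06% of random gene lists of the same size had a lower ratio, which is within their central 95%, so the variation between genes leaves both parts of the hypothesis open. In dextrose, 7 of 584 coding sites of 96-base intervals, 1.20% (95% interval 0.483 to 2.45), lay in essential complexes.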
